A study of Mus musculus with 2 samples.

How the data were processed

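Polyadenylated RNA longer than 200 bases from the hearts of 2 adult male mice of the B6NCrl strain, aged 8 weeks, had been sequenced as 1 library per mouse. Per the labels the libraries are biological replicates of 1 group, adult heart; both labels carry the same donor entry but each names an individual mouse with a sample of its own, so the libraries were treated as 2 mice. The deposited tables, 1 for genes and 1 for transcripts per library, hold values for the mm10 assembly and the GENCODE M4 annotation. The aligner and the quantifier are not given in the sources used here.

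Per the file headers, expected counts are estimated read numbers for each gene or transcript, in which the authors' model splits reads shared between transcripts, and they are not normalized. The deposited TPM values are the authors' abundances divided by effective length and scaled to the same total in every library, given as a maximum likelihood estimate and as a posterior mean estimate. The deposited FPKM values were made by the authors from the same counts, per length and per fragment total. The deposited isoform percent values are the percentage of its gene's TPM that the authors assigned to each transcript. Effective length was length minus 35 in nearly all entries, as for single reads of 36 bases. Totals were 11809591 and 11951044 expected counts, so that a count of 0, which allows up to 3 counts, corresponds to at most 0.254 and 0.251 CPM.

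The tables hold 43346 gene entries, 26248 transfer RNA entries and 97 spike-in entries. Symbols, gene types and GRCm38 positions were joined by gene ID without version from GENCODE M21, which matched 42462 gene entries, 21474 of them protein-coding. Transfer RNA and spike-in entries were kept in the totals but left out of the comparisons. The credibility bounds of TPM were not used here.

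The main settings, the gene lists and pairs, the rule for named genes and most alternatives were chosen before the data were examined. The named genes were the 20 nuclear protein-coding genes with the highest mean TPM, both members of the pairs with the 5 largest and 5 smallest log2 ratios together with Myh6 over Myh7, Atp2a2 over Atp2a1, Tnni3 over Tnni1, Actc1 over Acta1 and Pln over Sln, the 10 genes at each end of the log2 ratio between the mice among those past the filter, the 2 to 4 highest members of each list or the highest 1 for tissues that should be absent, the 4 members farthest from 0 of each list outside the random range, and the 10 cardiac genes with the largest second transcript or a leading transcript that differed.

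Libraries were scaled by TMM in edgeR 4.0.16 (R 4.3.3), with factors of 1.11 and 0.898, and the biological coefficient of variation was the root of edgeR's common dispersion over 12951 genes kept by filterByExpr, with both mice in 1 group. DESeq2 1.42.0 gave the alternative size factors and dispersion. Ratios between the mice are log2 of TMM-scaled counts of replicate 2 over replicate 1 with a prior count of 1. Intervals of these ratios and of shares of counts are exact Clopper-Pearson intervals at 95%, which cover counting error only; reads are not independent molecules. Ratios of gene pairs are log2 of TPM + 0.1, averaged over the mice, with a 95% interval from the robust spread between the mice of genes in the same of 20 expression bins. Counts of at least 10 over both libraries entered the chi-square test, log2(TPM + 1) of genes at 1 TPM or more in either library entered the correlation, and protein-coding genes with a mean of at least 1 TPM and 100 counts in either library entered the count of 2-fold differences. Leading transcripts were compared for genes with a mean of at least 5 TPM.

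The 45 gene lists hold 628 entries of 595 genes, of which Ahsp and Rn45s have no entry in the tables. They cover the contractile apparatus, calcium handling, ion channels, cardiac transcription factors, energy metabolism, the cell types of the heart, other tissues, and cell states. A list's median was set against 10000 random lists of the same size with 1 count or more, drawn for the ratio between the mice from the same 20 expression bins, and called outside beyond the central 95%. With 1 group no groups could be compared, and with 2 mice an exact sign-flip test cannot give a p below 0.5, so no p is given for single genes.

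The steps were tested on simulated libraries of 43346 genes with a coefficient of variation of 20%, without differences and with 200 changed genes. The coefficient came back as 0.195 without differences and 0.230 with them. Of the genes changed by log2 2 and 1.5, 96% and 92% were found past 2-fold in the right direction. A list of 15 raised genes lay at percentile 100, and 1% of 100 unchanged lists lay outside. The simulated genes varied independently of each other, which genes of 1 list may not do.

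Alternatives changed 1 choice at a time: pseudocount, filter, unit (FPKM, posterior mean TPM, expected counts), scaling (library size only, DESeq2 size factors), threshold, background, and each replicate left out. The comparison of lists in TPM with a pseudocount of 1 TPM changed unit, scaling and pseudocount together. Chosen after the data were seen were the chi-square test without mitochondrial, ribosomal-like and globin genes, 2 other totals for shares of TPM, the coefficient of variation, correlation and 2-fold count without 5 lists, and matching on the 200 genes nearest in expression. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.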

Results

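Polyadenylated RNA longer than 200 bases was sequenced from the hearts of 2 adult male B6NCrl mice, an inbred black mouse strain, at 8 weeks of age. The labels form 1 group with 2 biological replicates, each the heart of an individual mouse, and give no treatment, other tissue or other age. The questions are therefore which genes the adult heart expressed and how far the 2 hearts differed. The libraries, called replicate 1 and replicate 2 as in the labels, held 11809591 and 11951044 expected counts. Values are in TPM, the deposited abundance unit, which corrects for transcript length and has the same total in every library. They are given as mean ± SD over the 2 mice (n = 2) unless a replicate is named. Positions are those of the GRCm38 build.

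Transcripts of the mitochondrial genome were abundant in the heart libraries, and genes of the contractile apparatus were among the highest nuclear genes. The 13 mitochondrially encoded protein genes took 31.5% ± 1.23 of all TPM, led by the cytochrome c oxidase subunits mt-Co1 at 54184 ± 2496 TPM, mt-Co2 at 52656 ± 1939 TPM and mt-Co3 at 49303 ± 3298 TPM, and by cytochrome b, mt-Cytb, at 27333 ± 487 TPM. The highest nuclear protein-coding gene was Myl2, the ventricular regulatory myosin light chain (ENSMUSG00000013936, chromosome 5, 122100951 to 122113472), at 7304 ± 290 TPM. Leaving aside Lars2, treated separately, it was followed by myoglobin, Mb (ENSMUSG00000018893, chromosome 15, 77015487 to 77050670), at 4880 ± 80.4 TPM and by the tropomyosin gene Tpm1 (ENSMUSG00000032366, chromosome 9, 67022590 to 67049406) at 3967 ± 70.5 TPM. Cardiac troponin I, Tnni3, stood at 3629 ± 115 TPM and cardiac troponin T, Tnnt2, at 3627 ± 202 TPM.

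The other muscle genes among the 20 highest nuclear protein-coding genes were the light chain Myl3 at 2531 ± 158 TPM, cardiac actin, Actc1, at 2526 ± 87.3 TPM, the alpha myosin heavy chain, Myh6, at 2286 ± 51.8 TPM and cardiac troponin C, Tnnc1, at 1294 ± 73.8 TPM. Genes of mitochondrial energy supply filled most of the rest, with Atp5b at 1969 ± 87.4 TPM, Ndufa4 at 1659 ± 117 TPM and the adenine nucleotide carrier Slc25a4 at 1323 ± 8.59 TPM. The cytochrome c oxidase subunits among them were Cox6a2 at 1348 ± 53.4 TPM, Cox5b at 1275 ± 94.8 TPM, Cox7b at 1261 ± 14.7 TPM and Cox8b at 1216 ± 61.3 TPM. The fatty acid binding protein Fabp3 stood at 1399 ± 53.0 TPM. The adult globin genes Hba-a2 at 3485 ± 3363 TPM and Hbb-bs at 2787 ± 2608 TPM were the members of this set with an SD close to their mean. Lars2, which lay between Mb and Tpm1 at 4494 ± 999.8 TPM, completed the set and is a gene known to hold sequence that attracts ribosomal RNA reads. Together these 20 genes took 5.43% ± 0.583 of all TPM, and 22.7% ± 0.237 of the TPM of nuclear protein-coding genes, a total chosen after the data were seen. Protein-coding genes at 1 TPM or more in both mice numbered 9858 of 21474, of which 309 reached 100 TPM and 23 nuclear ones 1000 TPM in both.

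Several groups of entries weighed on these totals. Gm42418, Lars2, Mir6236 and the gene ID ENSMUSG00000045999 together took 15.7% of the counts of replicate 1 (95% exact binomial interval 15.68 to 15.72) and 19.2% of those of replicate 2 (19.21 to 19.25). The unprocessed pseudogenes Gm10925, Gm29216, Gm10222, Gm28439 and Gm28437, which lie side by side on chromosome 1 between 24611535 and 24616197, took 4.45% ± 0.152 of counts and 7.47% ± 0.121 of TPM. Of the 36-base words of these 5 pseudogenes, 99.6% also occur in mitochondrially encoded transcripts, so that their TPM values cannot be separated from those of the mitochondrial genes. The share of 31.5% given for the mitochondrially encoded protein genes leaves out any of their reads assigned to these pseudogenes. Gene entries under 150 bases took 18.8% ± 0.581 of TPM from 0.990% ± 0.0597 of counts.

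Contractile genes were highly expressed. In the thick filament list 13 of 14 members reached a mean of 1 TPM, with a list median of 163 TPM (177 in replicate 1 and 71.1 in replicate 2). Most members did not fall with that median, since after TMM scaling 9 were higher in replicate 2 and 5 lower. Beside Myl2, Myl3 and Myh6 the titin gene Ttn stood at 288 ± 7.14 TPM. In the thin filament list 13 of 14 members reached 1 TPM with a median of 84.5 TPM, led by Tpm1, Tnni3, Tnnt2 and Actc1. The Z-disc and intermediate filament list had 17 of 18 members at 1 TPM or more and a median of 119 TPM, led by the titin cap gene Tcap at 1063 ± 170 TPM, the small heat shock protein Cryab at 664 ± 13.1 TPM, Csrp3 at 496 ± 13.5 TPM and Myoz2 at 460 ± 22.6 TPM. Of the calcium handling genes 16 of 17 reached 1 TPM with a median of 58.0 TPM. The calcium pump of the sarcoplasmic reticulum, Atp2a2, stood at 899.5 ± 34.97 TPM, its inhibitor phospholamban, Pln, at 642 ± 22.0 TPM, S100a1 at 481 ± 12.4 TPM and Hrc at 267 ± 21.4 TPM. Ion channels and gap junction genes were lower, with 18 of 21 members at 1 TPM and a median of 5.43 TPM. The connexin Gja1 at 49.5 ± 3.14 TPM, Kcnip2 at 22.9 ± 0.177 TPM and the sodium channel Scn5a at 17.3 ± 1.64 TPM led them. Cardiac transcription factors had 24 of 29 members at 1 TPM and a median of 5.56 TPM, led by Esrra at 31.6 ± 2.12 TPM, Mef2d at 29.5 ± 4.01 TPM and Gata4 at 17.5 ± 3.72 TPM.

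Every member of the nuclear lists of energy metabolism reached 1 TPM. The median was 536 TPM over 27 genes of respiratory complexes II to IV, 522 TPM over 15 genes of ATP synthase and 244 TPM over 36 genes of complex I. In ATP synthase Atp5b was followed by Atp5g3 at 1162 ± 42.4 TPM, and in complex I Ndufa4 was followed by Ndufa3 at 657 ± 9.39 TPM. The tricarboxylic acid cycle had a median of 143 TPM over 18 genes, led by Mdh2 at 392.1 ± 2.26 TPM and Sdhb at 299 ± 5.13 TPM. Fatty acid uptake and oxidation had a median of 93.0 TPM over 23 genes, where Fabp3 was followed by lipoprotein lipase, Lpl, at 444 ± 6.10 TPM and Etfb at 317 ± 1.18 TPM. Glycolysis and glucose uptake had a median of 82.0 TPM over 19 genes, led by Aldoa at 731 ± 0.615 TPM and Ldhb at 595 ± 11.3 TPM. Creatine and ketone metabolism had a median of 22.8 TPM over 9 genes, led by the creatine kinases Ckmt2 at 556 ± 17.0 TPM and Ckm at 444 ± 32.3 TPM. The 41 cytosolic ribosomal protein genes had a median of 171 TPM, with Rplp1 at 460 ± 60.4 TPM and Rps15 at 396 ± 41.4 TPM at the top. The 12 housekeeping genes had a median of 62.2 TPM, with Gapdh at 276 ± 11.02 TPM and Sdha at 230 ± 4.05 TPM.

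Lists of markers of the cell types of the heart had medians from 2.15 to 26.6 TPM. All 16 endothelial markers reached 1 TPM with a median of 26.6 TPM, led by Fabp4 at 281 ± 28.9 TPM and Ly6c1 at 213 ± 22.0 TPM. All 14 fibroblast and matrix markers reached 1 TPM with a median of 14.7 TPM, led by Gsn at 228 ± 103 TPM and decorin, Dcn, at 130 ± 61.4 TPM. The smooth muscle and pericyte list had 10 of 11 members at 1 TPM and a median of 7.35 TPM, with Rgs5 at 93.4 ± 10.5 TPM and Smtn at 44.8 ± 12.5 TPM. All 11 macrophage markers reached 1 TPM with a median of 5.66 TPM, led by Lyz2 at 65.8 ± 15.1 TPM and C1qa at 31.1 ± 3.97 TPM. Endocardial and lymphatic markers had 7 of 8 members at 1 TPM and a median of 5.75 TPM, with Cytl1 at 13.1 ± 10.9 TPM and Ccl21a at 9.08 ± 0.255 TPM. All 8 mesothelial and epicardial markers reached 1 TPM with a median of 2.15 TPM, led by Upk3b at 7.94 ± 8.36 TPM and Msln at 4.18 ± 4.35 TPM. The 13 atrial markers all reached a mean of 1 TPM with a median of 7.79 TPM, which was 14.6 TPM in replicate 1 and 3.78 TPM in replicate 2, where Dkk3, Bmp10, Gja5, Nr2f1 and Fgf12 were under 1 TPM. Of 7 ventricular markers 5 did so, with a median of 22.9 TPM.

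Most genes of cell types that should be rare or absent in heart were low, with the liver and erythroid lists as exceptions. None of the 10 lymphocyte, 6 lung, 5 thymus and 6 white adipocyte markers reached a mean of 1 TPM. Their highest members were Cd79b at 0.675 ± 0.276 TPM, Scgb1a1 at 0.805 ± 1.14 TPM, Cd8b1 at 0.115 ± 0.0778 TPM and Cfd at 0.710 ± 1.00 TPM. Of the 9 neutrophil and mast cell markers 1 reached that level, S100a9 at 1.87 ± 1.00 TPM, as did 1 of 11 Schwann cell and neuron markers, Plp1 at 1.40 ± 0.297 TPM, and 1 of 12 cell cycle genes, Rrm2 at 1.07 ± 0.368 TPM. The skeletal muscle list had 2 of 13 members at 1 TPM, the highest being the fast light chain Myl1 at 57.2 ± 35.9 TPM, with a list median of 0.190 TPM. The brown adipocyte list had 3 of 6 at that level, among them Cox7a1 at 1049 ± 61.3 TPM and Cpt1b at 62.0 ± 11.02 TPM, which cardiomyocytes express, while Ucp1 had 0.0500 TPM in replicate 1 and 0 in replicate 2. All 6 liver markers exceeded a mean of 1 TPM, with albumin, Alb, at 77.0 ± 87.5 TPM. Their median of 8.52 TPM was 14.8 TPM in replicate 1 and 2.21 TPM in replicate 2, where Apoh and Fgb were under 1 TPM. Of the erythroid markers, 7 of 9 erythroid markers did so with a median of 21.4 TPM.

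Lists of cell state gave intermediate levels. The fetal and stress genes of the heart had 10 of 12 members at 1 TPM and a median of 48.7 TPM. Nppa, which is also an atrial marker, led it at 762 ± 858 TPM, and Ankrd1 stood at 147 ± 32.0 TPM. Heat shock genes had a median of 31.7 TPM with Hspa8 at 330 ± 22.8 TPM. Major histocompatibility genes had a median of 17.8 TPM with B2m at 215 ± 20.1 TPM, and glucocorticoid and fasting genes one of 9.79 TPM with the metallothionein Mt1 at 381 ± 34.1 TPM. Medians were 8.16 TPM for hypoxia genes, led by Vegfa at 62.8 ± 7.74 TPM, and 5.92 TPM for circadian clock and output genes, led by Tef at 50.1 ± 10.2 TPM and Dbp at 36.9 ± 14.998 TPM. They were 4.90 TPM for interferon genes, led by Ifi27l2a at 34.0 ± 10.1 TPM, and 3.41 TPM for immediate early genes, led by Klf2 at 19.0 ± 4.27 TPM. Among the 5 sex-linked genes, with a median of 2.80 TPM in these males, Eif2s3y stood at 12.6 ± 1.43 TPM and Xist at 0.0800 and 0.0600 TPM. The list of non-polyadenylated and nuclear RNA had a median of 105 TPM, led by the mitochondrial ribosomal RNA genes mt-Rnr1 at 28383 ± 2241 TPM and mt-Rnr2 at 23785 ± 769 TPM. Against 10000 random lists of the same size drawn from protein-coding genes with at least 1 count, the medians of 26 of the 45 lists lay above the central 95%, 8 below and 11 within it. The 8 were the lymphocyte, lung, thymus, white adipocyte, neutrophil and mast cell, Schwann cell and neuron, cell cycle and skeletal muscle lists. Medians in replicates 1 and 2 also lay more than 1.5-fold apart for the erythroid list (34.8 and 8.10 TPM), the mesothelial list (3.51 and 0.970 TPM), the endocardial and lymphatic list (6.85 and 2.93 TPM), the fibroblast list (18.2 and 11.4 TPM), the fetal and stress list (56.1 and 33.9 TPM), the circadian list (7.57 and 4.48 TPM), the sex-linked list (3.71 and 2.05 TPM) and the skeletal muscle list (0.350 and 0.0400 TPM). Sparse lists did so too, namely the cell cycle list (0.375 and 0.220 TPM), the neutrophil and mast cell list (0.420 and 0.160 TPM) and the Schwann cell and neuron list (0.110 and 0.0400 TPM), and the medians of the white adipocyte, lung and thymus lists were 0.315, 0.025 and 0.01 TPM in replicate 1 and 0 in replicate 2.

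In most of 32 gene pairs the first gene outweighed the second. Many pairs set an adult cardiac gene over one typical of other muscle or of the fetal heart. Others do not, such as Nppa, itself on the fetal and stress list, over Nppb. Cardiac troponin I, Tnni3, exceeded the slow skeletal and fetal form Tnni1 by a log2 ratio of 13.12 ± 0.64, at 3629 against 0.330 TPM. Tnni1 had 6 counts in replicate 1 and 2 in replicate 2, and the 95% interval of the ratio was 12.03 to 14.22. The log2 ratio was 10.28 ± 0.87 for the calcium pumps Atp2a2 over Atp2a1, 9.03 ± 0.07 for the ryanodine receptors Ryr2 over Ryr1, 8.70 ± 0.61 for Tpm1 over Tpm2 and 8.06 ± 0.04 for Tnnt2 over Tnnt1. The adult alpha myosin heavy chain Myh6 exceeded the beta chain Myh7 by 5.42 ± 0.29, or 42.8-fold, and cardiac actin, Actc1, exceeded the skeletal form Acta1 by 4.90 ± 0.03, or 29.8-fold. The smallest ratios were 0.04 ± 0.25 for the sodium pumps Atp1a1 over Atp1a2, -0.49 ± 0.15 for Myom2 over Myom1, 0.97 ± 0.38 for Adrb1 over Adrb2, 1.06 ± 0.13 for Ppara over Pparg and 1.19 ± 0.19 for Hk2 over Hk1. Over all 32 pairs the first gene was higher in 30, lower in 1 and not separable in 1, Atp1a1 over Atp1a2, with respect to a 95% interval from the spread of genes at the same level. In 21 pairs the mean difference was at least 10-fold. Some of these were under 10-fold in 1 mouse. The log2 ratio was 2.06 for Nppa over Nppb in replicate 2. In replicate 1 it was 2.51 for Myl3 over Myl4, 3.26 for Cpt1b over Cpt1a and 3.31 for Eno3 over Eno1. Ratios to genes near 0 depended on the pseudocount of 0.1, since with 1 in its place those of Tnni3, Atp2a2 and Ryr2 were 11.42, 9.08 and 5.90.

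Pairs with an atrial gene differed strongly between the mice. The ratio of phospholamban to sarcolipin, Pln over Sln, was 1.01 in replicate 1 and 5.60 in replicate 2 on the log2 scale. Further such pairs, singled out after their values were seen, were Myl2 over Myl7 at 3.84 and 8.02, Myl3 over Myl4 at 2.51 and 6.86, Gja1 over Gja5 at 3.60 and 5.44, and Nppa over Nppb at 4.78 and 2.06. The pooled interval is too narrow for these pairs. With 2 mice no exact sign-flip test can give a p below 0.5, so none is given.

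**Figure D1:**
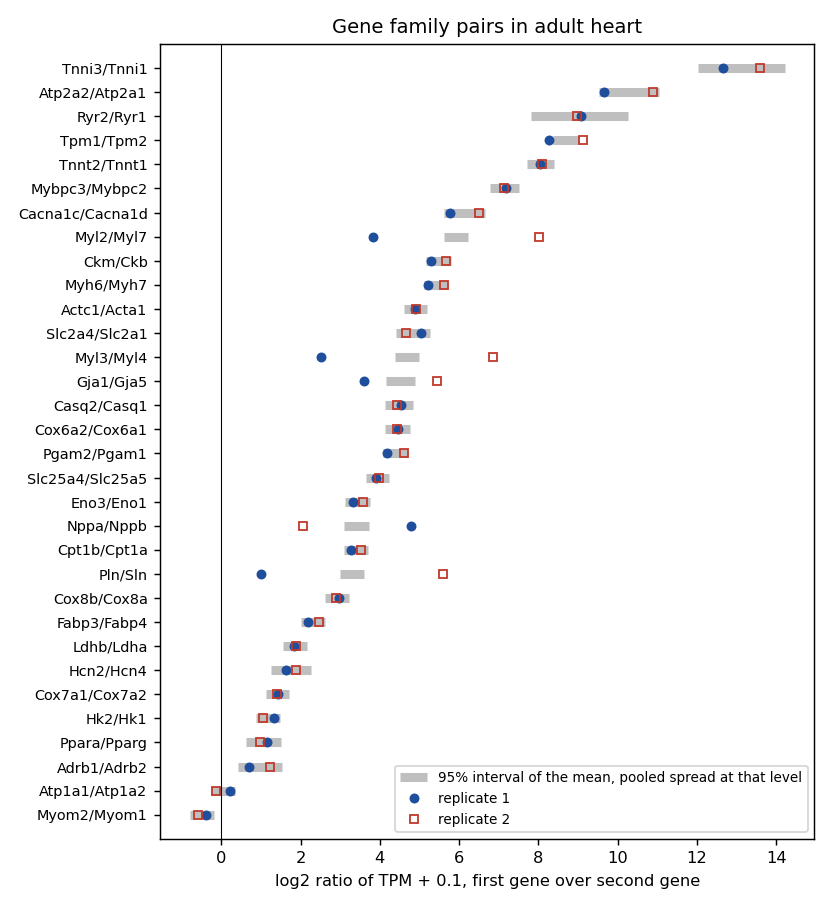
Log2 ratio of TPM + 0.1 of the first over the second gene of 32 gene pairs, with replicate 1 as filled circles, replicate 2 as open squares and the 95% interval of the mean, from the pooled spread at that expression level, as grey bars. Tnni3 over Tnni1 is at the top with a mean of 13.12, and the symbols of Pln over Sln lie far apart, at 1.01 and 5.60.

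Expression in the hearts was compared gene by gene. A chi-square test of the rounded counts of the 2 libraries, which sets separate animals against counting error alone and so exceeds it in any case, gave 303176.5 on 15483 degrees of freedom, or 19.6 per degree of freedom, and 8.40 without mitochondrial, pseudogene, ribosomal-like and globin genes, a set chosen after the data were seen. Across 12893 genes at 1 TPM or more in either library, which are not independent replicates, log2(TPM + 1) had a Pearson r of 0.960 and a Spearman rho of 0.935. The biological coefficient of variation was 16.7% over 12951 genes. TMM scaling set the effective size of replicate 2 to 81.7% of that of replicate 1. With library size only, the median log2 ratio of the genes compared below moved from 0.02 to -0.29. After scaling the log2 ratio still varied with level, with a median of -0.05 for protein-coding genes at 1 to 10 TPM, 0.08 at 10 to 100 TPM and 0.25 at 100 TPM or more.

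**Figure D2:**
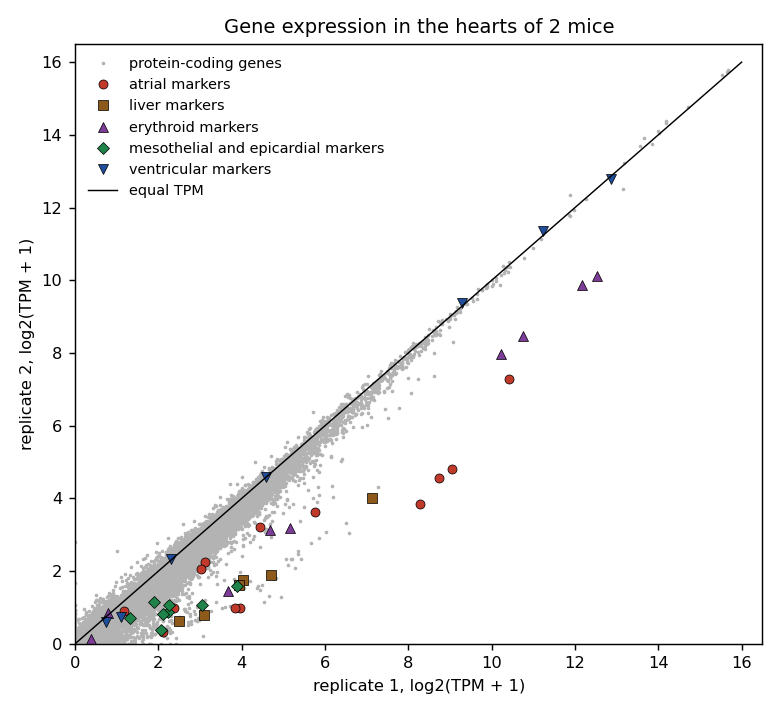
Log2(TPM + 1) of protein-coding genes in replicate 1 (horizontal axis) and replicate 2 (vertical axis), 1 grey point per gene, with markers of 5 lists in colour and the line of equal TPM. Ventricular markers such as Myl2 lie close to the line, and atrial, liver, erythroid and mesothelial markers lie below it, for example Sln at 312 TPM in replicate 1 and 13.4 TPM in replicate 2.

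Atrial transcripts were much lower in replicate 2. All 13 atrial markers were lower there, with a median log2 ratio of replicate 2 over replicate 1 of -2.81. Sarcolipin, Sln (ENSMUSG00000042045, chromosome 9, 53850164 to 53854560), had 312 TPM in replicate 1 and 13.4 TPM in replicate 2, a log2 ratio of -4.19 (95% interval -4.54 to -3.89). The atrial light chains Myl7 and Myl4 had 526 and 425 TPM in replicate 1 and 27.3 and 22.7 TPM in replicate 2, Dkk3 had 14.6 and 0.970 TPM, and atrial natriuretic peptide, Nppa, had 1369 and 155 TPM. The ventricular light chain Myl2 stood at 7509 and 7099 TPM, and the ventricular list had a median log2 ratio of 0.27, within the central 95% of random lists. It lay above that range with TPM and a pseudocount of 1 TPM (median 0.02) or with members at 1 TPM or more alone (0.35), and its median was -0.04 with library size only. The interval, here and below, is exact and covers counting error only.

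Liver, red cell and mesothelial transcripts were lower in replicate 2 as well. All 6 liver markers had a median log2 ratio of -2.77, with Alb (chromosome 5, 90460897 to 90476602) at 139 and 15.1 TPM (log2 ratio -2.87), Ttr at 25.0 and 2.72 TPM, Apoh at 7.52 and 0.740 TPM and Fgb at 4.65 and 0.550 TPM. All 9 erythroid markers were lower, with a median of -1.92. The alpha globin Hba-a2 had 5863 and 1108 TPM, the beta globin Hbb-bs 4632 and 943 TPM, Hba-a1 1724 and 352 TPM and Snca 11.7 and 1.73 TPM. The globin genes took 0.866% of counts (95% interval 0.861 to 0.871) in replicate 1 and 0.172% (0.169 to 0.174) in replicate 2. Reads shared by the near-identical globin copies were split between them by the authors' model, and the summed globin counts were 4.07-fold lower in replicate 2. All 8 mesothelial and epicardial markers were lower, with a median of -1.77; Lrrn4 gave -2.94, Upk3b -2.42, Msln -2.34 and Krt19 -1.78.

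Fibroblast, endothelial and clock genes differed by less in the same direction. Of 14 fibroblast and matrix markers 13 were lower in replicate 2, with a median log2 ratio of -0.65, -1.34 for Tcf21, -1.17 for Lum, -0.94 for Fbln1 and -0.93 for Postn. Of 16 endothelial markers 11 were lower, with a median of -0.13, -1.29 for Vwf, -0.71 for Eng, -0.40 for Emcn and -0.36 for Tek. Of 16 circadian clock and output genes 15 were lower, with a median of -0.33, -0.71 for Arntl (interval -1.84 to 0.24), -0.55 for Per2, -0.54 for Ciart and -0.51 for Cry2. In the endocardial and lymphatic list 6 of 8 were lower, with a median of -0.55. Npr3 gave -2.07, Cytl1 -1.62 and Lyve1 -0.92. Hapln1 had 7 counts in replicate 1 and 0 in replicate 2, or 1.91-fold lower against a floor of 3 counts per library. Folds against the floor, here and below, leave out the counting error of the other library. The exact upper limit of the log2 ratio of Hapln1 was -0.24, which allows a smaller fold. This list was within the random range with TPM and a pseudocount of 1 TPM, which changes unit, scaling and pseudocount together, or with members at 1 TPM or more alone.

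Sparse lists on this side rested on few counts. In the lung list Scgb1a1 had 9 counts in replicate 1 and 0 in replicate 2 (2.45-fold lower against the floor, upper limit of the log2 ratio -0.69). Sftpc had 5 and 0 and Ager 1 and 2. The median of -2.29 became -1.08 with the zeros at 3 counts and Ager, which is under that floor, left out. In such medians the prior count of 1 was added to the counts but not to the floor. Their ratios are therefore larger in size than the folds against the floor, which use no prior count. In the white adipocyte list Cfd had 16 counts and 0 (4.36-fold lower against the floor, upper limit -1.66) and Adipoq 6 and 0. Lep and Plin1 had 2 and 0, and the median of -1.29 became -0.93 in the same way, over the 3 members above 3 counts. In the neutrophil and mast cell list Ngp had 5 counts and 0, Camp 3 and 0, Mcpt4 11 and 2 (log2 ratio -1.71, interval -5.38 to 0.03) and S100a8 2 and 6 (1.51, interval -0.61 to 5.22), and the median of -1.29 became -0.03. Of the 9 members 3 were higher in replicate 2 and 6 lower, and their summed TPM was nearly equal, at 4.49 in replicate 1 and 4.41 in replicate 2. For Sftpc, Adipoq and Ngp, with upper limits of 0.42, 0.06 and 0.42, no difference was detectable at this depth.

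Lists of energy metabolism and of the Z-disc had slightly higher medians in replicate 2 after TMM scaling, a direction that turned for most of these lists with library size only or TPM. Protein-coding genes at 100 TPM or more had a median of 0.25 as a whole. ATP synthase at 0.27 and creatine and ketone metabolism at 0.22 lay within the random range, and the 9 lists that follow lay above it. The median log2 ratio was 0.43 for the 13 mitochondrially encoded genes, where mt-Nd6 gave 0.59, mt-Nd1 0.51 and both mt-Nd3 and mt-Co3 0.47, and mt-Nd4l was the 1 gene that was lower. It was 0.32 for the Z-disc and intermediate filament list (Myot 0.76, Fhl2 0.52, Des 0.46; Myoz1 had 1 count and 0), 0.31 for the tricarboxylic acid cycle (Dlst 0.52, Sdhd 0.50, Aco2 0.41, Ogdh 0.37) and 0.31 for glycolysis (Hk1 0.46, Eno3 0.41, Pgam2 0.40, Gapdh 0.39). It was 0.30 for complex I (Ndufa12 0.45, Ndufs4 0.42, Ndufs6 and Ndufs7 0.38) and 0.30 for complexes II to IV (Sdhd 0.50, Uqcr11 0.44, Cycs 0.40, Uqcrq 0.35). Fatty acid oxidation gave 0.27 (Eci1 0.44, Fabp3 0.41, Cpt2 0.36, Acsl1 0.35), the major histocompatibility genes 0.26 (H2-Aa 0.90, Cd74 0.53, H2-Ab1 0.50, H2-Eb1 0.48). The cardiac transcription factors gave 0.16, and their farthest members were Gata5 at -1.58 (9.83 counts and 2, interval -5.26 to 0.20), Tbx5 at -0.83 and Esrrb at 0.70, with Hand1 at 0 counts and 1. With library size only the medians of 6 of the 9 lists above the random range turned negative, and with TPM and a pseudocount of 1 TPM those of 7. The mitochondrially encoded list stayed positive under both, at 0.12 and 0.09, as did the Z-disc list, at 0.0064 and 0.0092. The random range of the mitochondrially encoded list came mostly from genes at far lower levels. Its lowest member, mt-Nd4l, stood at 7429 TPM, and the top expression bin had a median of 54.9 TPM.

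Against 10000 random lists matched on expression, 20 of the 45 lists lay outside the central 95%, 11 lower and 9 higher in replicate 2. Lists of unrelated genes would give 2.25. Genes of 1 list may vary together between hearts and some lists share genes, so the excess over 2.25 is no test. In every setting tried, 7 of the lower lists (atrial, liver, erythroid, mesothelial, fibroblast, endothelial, circadian) and 5 of the higher ones (mitochondrially encoded, Z-disc, tricarboxylic acid cycle, glycolysis, complex I) stayed outside on the same side. Library size only and DESeq2 size factors move all ratios alike and leave a list's place nearly fixed, so they are no check. The check rests on TPM with a pseudocount of 1 TPM, members at 1 TPM or more alone, and matching on the 200 nearest genes. Matching on level fails for the mitochondrially encoded list. Few genes reach its level, and the top expression bin had a median of 54.9 TPM, so its place is no support. The lung list and the neutrophil and mast cell list could not be run with members at 1 TPM or more alone, and with zeros at 3 counts their medians of -1.08 and -0.03 would lie within the random ranges of -2.03 to 1.29 and -1.03 to 0.65 found without that floor. Among the higher lists, complexes II to IV were within the random range with matching on the 200 genes nearest in expression, chosen after the data were seen, fatty acid oxidation with that matching or with members at 1 TPM or more, and the major histocompatibility and cardiac transcription factor lists with TPM and a pseudocount of 1 TPM. The white adipocyte list was within it with that matching or that unit. The other 25 lists were within the random range in the main setting. Under alternatives the fetal and stress list lay below it in 3, calcium handling and ventricular markers above it in 2, and immediate early genes and skeletal muscle below it in 1. None of these alternatives was a change of scaling factor alone. With library size only, each positive median below turned negative. Among lists of muscle and metabolism the median was 0.27 for calcium handling, ventricular markers and ATP synthase, 0.25 for thick filament, 0.22 for creatine and ketone metabolism, 0.21 for thin filament, 0.16 for ribosomal proteins and 0.13 for ion channels. State lists gave 0.23 for heat shock, 0.18 for hypoxia, 0.07 for interferon, -0.03 for housekeeping, -0.08 for fetal and stress, -0.11 for glucocorticoid and fasting, -0.18 for immediate early and -0.53 for cell cycle genes. Nppa, Myl7 and Myl4 of the fetal and stress list are also atrial markers and were lower by the values above. Non-polyadenylated RNA gave 0.07, smooth muscle and pericytes -0.04, sex-linked genes -0.10, macrophages -0.15, Schwann cells and neurons -0.22, lymphocytes -0.40, skeletal muscle -0.71 and brown adipocytes -0.34. Over members above 3 counts, with zeros at 3 counts, the median became 0.12 for brown adipocytes (4 members) and -0.93 for lymphocytes (7). It became -0.086 for Schwann cells and neurons (5) and -0.80 for skeletal muscle (8). No thymus marker was above 3 counts.

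**Figure D3:**
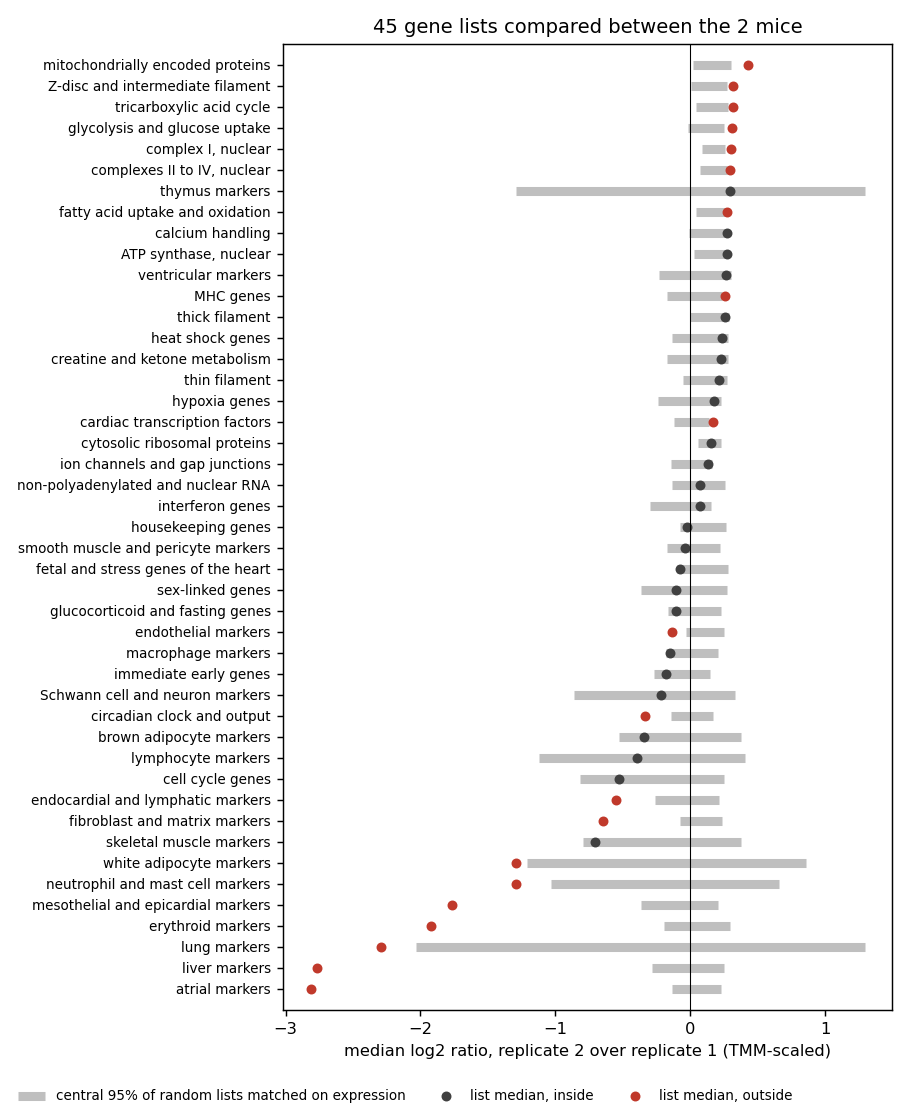
Median log2 ratio of replicate 2 over replicate 1 of 45 gene lists after TMM scaling (points) and the central 95% of 10000 random lists matched on expression (grey bars). Points outside the bars are red; the atrial list, at -2.81, and the liver list, at -2.77, lie farthest below 0.

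Single genes differed almost only in the direction of lower values in replicate 2. Of 7269 protein-coding genes with a mean of at least 1 TPM and 100 counts in either library, 162 (2.23%) differed at least 2-fold, 159 lower and 3 higher in replicate 2. The 10 lowest included the atrial genes Sln, Myl7, Myl4, Dkk3 and Bmp10 at log2 ratios of -4.19, -3.93, -3.87, -3.55 and -3.38. Also among them were Mybphl, a myosin binding protein gene, at -4.00 and Tmem163 at -3.68. The rest were the major urinary protein genes Mup2, Mup11 and Mup7, near-identical copies made by the liver, at -3.77, -3.77 and -3.42. The 10 highest were Tgtp1 at 1.08, Gm10801 at 1.04, Gm10800 at 1.01, Klhdc8a at 1.00, the class II histocompatibility gene H2-Aa at 0.90, Timm22 at 0.86, Ankrd23 at 0.85, Sh3rf2 and Dusp18 at 0.82 and Gpr22 at 0.81. The first 3, which alone were past 2-fold, had fractional counts in both mice (61.21 and 105.64, 72.38 and 121.58, 405.24 and 669.35). Part of their reads was thus split with other entries by the authors' model. Without the atrial, liver, erythroid, mesothelial and fibroblast lists, a selection made after the data were seen, 136 of 7228 genes were past 2-fold, 133 of them lower. These still held genes of hepatocytes outside the liver list, such as Apob at -3.32, Fga at -3.00 and Ahsg at -2.68, chosen after their values were seen, and the Mup genes and Mybphl named above. Libraries simulated with counting error only gave 0 of 7269 genes past 2-fold. Libraries simulated without any difference but with a coefficient of variation of 20% gave 2.18% of 7291 genes, 91 lower and 68 higher. That coefficient is above the 16.7% measured here in the main setting. Alternatives gave 0.224 with DESeq2's median gene dispersion and 0.235 with library size only, and the others 0.154 to 0.188. The simulated share of genes therefore cannot serve as a chance rate. With 1 library per mouse these differences have no replicate check, and no p is given across genes.

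Among 4143 protein-coding genes with a mean of at least 5 TPM and 2 or more annotated transcripts, the leading transcript took a median share of 48.6%, and this share differed between the mice by a median of 5.27 percentage points. In 872 genes (21.05%) another transcript led in replicate 2 than in replicate 1. In 31 of these the leading transcript was ahead by at least 20 points on average, a condition that a switch itself makes rare. Of 22 cardiac genes chosen in advance 21 had 2 or more transcripts, and Vegfa alone changed its leading transcript, with nearly equal shares of 19.5% and 21.8% for Vegfa-201 and 18.1% and 21.8% for Vegfa-207.

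The second transcripts with the largest shares were Sorbs1-201 at 37.4% ± 2.16 behind Sorbs1-202 at 44.6% ± 1.76, Fxr1-201 at 34.1% ± 0.820 behind Fxr1-202 at 65.9% ± 0.820, and Mef2c-203 at 31.1% ± 3.52 behind Mef2c-202 at 57.2% ± 6.57. The dystrophin transcript Dmd-203 took 28.4% ± 1.36 and the non-coding Dmd-210 32.8% ± 3.52. Second transcripts took 24.4% ± 1.85 in Mef2d, 20.4% ± 0.0990 in Tpm1, 20.3% ± 0.148 in Pdlim5, 19.95% ± 2.60 in Vegfa, 19.8% ± 5.12 in Slc25a3 and 17.3% ± 2.24 in Cacna1c. Those of Slc25a3 and Cacna1c, and the leading transcript of Mef2d, are annotated as non-coding like Dmd-210. The shares come from the authors' model, which divides 36-base reads among transcripts that overlap.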

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

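Of the tests below, that of the fetal and stress genes and that of scaling were chosen only after the result was seen. Signal in entries outside the comparisons drew attention because it exceeded the 3 counts that a count of 0 allows: the 97 spike-in entries held 13.92 counts in replicate 1 and 13 in replicate 2, of which ERCC-00054 held 11.92 and 12, and the 26248 transfer RNA entries held 2081.2 and 1207.8 counts. The labels name a spike-in reference, but the amount added is not given in the sources used here, so these counts give no recovery. Explanations by other tissue or cells in the sample are treated as technical here; of biological ones the fetal and stress program alone was tested, since the labels give 1 group.

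Atrial transcripts were lower in replicate 2, by a median log2 ratio of -2.81 over 13 of 13 markers. A fetal and stress program of the ventricle in replicate 1 is argued against by the 8 fetal and stress genes outside the atrial list. Their median was 0.25 where -1 or lower was required. Scaling is argued against by the distance of the atrial median from the 2.5th percentile of random lists matched on expression, -2.67. A scaling factor moves genes of the same level alike. That distance restates the values that put the atrial list outside the random range, so it is no separate test. Less atrial tissue in the sample of replicate 2 may account for the pattern and stays open. A second list of atrial and sinus node genes gave a median of -0.27 over 7 genes with at least 20 counts, 5 of them lower, from -2.80 for Cacna2d2 to 0.47 for Kcnk3. This lay between the bounds set for and against that explanation, -0.5 and -0.2, and several members are also expressed in ventricle, so less atrial tissue and another source of the difference cannot be told apart.

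Liver transcripts were lower in replicate 2, by a median log2 ratio of -2.77 over 6 of 6 markers, with Alb at 139 TPM in replicate 1. A second list of hepatocyte genes that shares no gene with the first gave a median of -2.66 over 17 genes with at least 20 counts, all 17 lower, and of -2.65 with Otc, at 21 counts and 0, set to the floor of 3 counts; Fah, at -0.29, differed least. Liver RNA in the sample of replicate 1 is therefore a candidate explanation; whether it came with the tissue or from another library was not tested. Carry-over from libraries of several other organs is argued against for the organs covered: 2 of 20 genes of kidney, testis, pancreas, intestine and brain had at least 10 counts in replicate 1, where 5 were required. These were Slc17a7 and Camk2a, which had 93 and 371 counts in replicate 2 too. Lung and fat were not covered. Of their markers, Scgb1a1 had 9 counts in replicate 1 and 0 in replicate 2 and Cfd 16 and 0, while Ager had 1 and 2.

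Hemoglobin transcripts were lower in replicate 2, with Hba-a2 at 5863 and 1108 TPM. Uneven splitting of reads between the globin copies is argued against by the log2 ratio of their summed counts, -2.03. Red blood cell RNA left in the tissue of replicate 1 is a candidate explanation: the erythroid genes other than globins with at least 20 counts had a median log2 ratio of -1.52 over 4 genes, past the bound of -1 set for it. Whether more blood stayed in that heart or its blood held more immature red cells was not tested.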

How the results depend on the processing

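The totals of protein-coding genes alone, the chi-square test without gene groups and the matching on 200 genes were tests chosen only after the result was seen. The correlation of 0.960 became 0.893 and 0.980 with pseudocounts of 0.1 and 5, 0.973 with no filter and 0.974 with posterior mean TPM. Detected genes were 4649 at 5 TPM. Genes past 2-fold numbered 347 of 10474 at 10 counts and 19 of 744 at 1000 counts, and genes with another leading transcript 2202 of 7913 at 1 TPM and 48 of 481 at 50 TPM, where the number of genes tested differs. The mitochondrially encoded share was 28.7% with posterior mean TPM and 56.9% of protein-coding TPM, the share of the top 20 genes 7.11% of counts, 10.4% without mitochondrially encoded genes and 22.7% of nuclear protein-coding TPM, and the chi-square 8.40 per degree of freedom without mitochondrial, pseudogene, ribosomal-like and globin genes. With library size only, the median log2 ratio reversed for MHC genes (-0.054), cardiac transcription factors (-0.15), complex I (-0.0090), complexes II to IV (-0.013), fatty acid oxidation (-0.036) and glycolysis (-0.00057), and with TPM and a pseudocount of 1 for these lists (-0.21, -0.13, -0.023, -0.039, -0.044, -0.039) and the tricarboxylic acid cycle (-0.0095), as these settings moved the median of the 7269 genes compared from 0.02 to -0.29 and -0.26. Leaving out each replicate gave 9953 to 10883 detected genes, shares of 30.6% to 32.4% and 5.01% to 5.84%, 29 to 30 pairs with the first gene higher and 26 to 27 lists above the random range. In 7 further cases a list outside the random range lay within it under an alternative (endocardial, fatty acid oxidation and white adipocyte lists in 2 each, complexes II to IV in 1), and in 9 a list within it lay outside (fetal and stress genes in 3, calcium handling and ventricular markers in 2 each, immediate early genes and skeletal muscle in 1 each). In all, 38 comparisons of a pair ratio with an alternative moved by more than 1 SD without changing sign, and 39 main and 342 other comparisons with an alternative kept their call or stayed within 1 SD or 1.5 times. Among these, lists within the random range changed sign with the scaling, and Atp1a1 over Atp1a2, not separable from 0, was -0.12 with expected counts and -0.14 without replicate 1. Library size only and DESeq2 size factors move all ratios alike, so whether a list lay outside the random range was nearly fixed under them. Unless stated, the cause was not tested. Depth limited genes under 3 counts per library, and with 2 mice no difference between them has a replicate. No paired analysis was possible because there is 1 group.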

Other observations

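The genes in this paragraph were chosen after their values were seen. Among further genes lower in replicate 2, the log2 ratio was -3.00 for the chemokine gene Ppbp, -1.99 for Nrgn and -1.91 for Plek. The kinase genes Sbk3 and Sbk2 gave -3.05 and -1.90, the iron hormone gene Hamp -3.14 and the cadherin gene Cdh11 -2.93.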
